A study of Mus musculus with 2 samples.

How the data were processed

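Dimethylation of histone H3 at lysine 4 (H3K4me2), a mark of active and primed promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in kidneys of mouse embryos at embryonic day 16.5. Per the labels, the series holds 2 biological replicates of 1 group, each from its own pool of embryos, and the pool of replicate 2 came from 41 embryos. There is no second tissue, stage or treatment, so the only comparison of samples is between the replicates. All other comparisons set genes or regions against each other within these libraries.

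The data are 4 peak lists in narrowPeak form on mouse assembly mm10, per the deposited descriptions of the files: a list called in each replicate, a list called on both replicates pooled, and a list of replicated peaks derived from those lists. The rule by which a pooled peak became a replicated peak, the aligner, the peak caller and its threshold are not given in the sources used here. For each peak the authors deposited a signal column, called the enrichment value below, whose scale and control are not stated in those sources. It was used to describe, rank and filter peaks, and to order promoters by the mean of the highest value at each promoter in both replicate lists. The authors also deposited −log10 p and −log10 q columns, and the position of the summit. The lowest −log10 p was 2.01 in replicate 1, 2.02 in replicate 2, 2.03 in the pooled list and 2.27 in the replicated list. Peak lists hold no read counts, so the sequencing depth of the libraries is unknown and no value below has an error from read counting.

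Gene positions came from the basic set of GENCODE M21 on assembly GRCm38, the same build as mm10. Transcription start sites (TSS) of protein-coding and long noncoding RNA genes gave 56544 different positions. Each base of chromosomes 1 to 19, X and Y was put in a class in the order promoter (within 1 kb of a TSS), exon, intron, intergenic, and each peak took the class of its midpoint. Expected shares came from all called bases. Of the 21851 protein-coding genes, a gene counted as marked when a replicated peak overlapped 1 kb on either side of any of its protein-coding TSS. Such a peak can belong to a neighbour with a nearby TSS. Distal peaks had midpoints over 1 kb from every TSS and were counted within 50 kb of the principal TSS of each gene. Promoter CpG content was the observed over expected CpG ratio within 500 bp of that TSS. Coordinates are 1-based.

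Replicate lists were compared by overlap, a peak counting as shared when at least 50% of it or of its partner was covered, and by Spearman's rho across replicated peaks. Shares have exact Clopper-Pearson intervals at 95%, and values from the replicate lists have an SD with n = 2. In total 23 gene lists with 426 members were used, covering kidney compartments, other cells the organ holds, other tissues, housekeeping genes and Hox genes. They hold 416 different genes, of which 10 stand on more than 1 list, and 1 symbol (Ahsp) had no match in the annotation. Promoter marking of each list was compared with all other protein-coding genes by a 2-sided Fisher's exact test. The mean number of distal peaks of each list was compared with 100000 random lists of equal size by a 2-sided permutation test, in which 2e-05 is the smallest p possible. Matches to 23 consensus motifs within 250 bp of distal summits were compared with the same sequences shuffled with dinucleotide counts kept, by Fisher's exact test, and a motif was called at a ratio of at least 1.2 and an adjusted p under 0.05. Each family of tests was adjusted by the Benjamini-Hochberg method. Replicated peaks up to 1 kb apart were joined into domains and ranked by width. Genes and peaks are the units of these tests and are not replicates, so p-values describe these libraries, not the spread between embryos.

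Lists, motifs, tests and the rule for genes to name were chosen before the data were examined. The rule took the 2 highest and 2 lowest members of each list by mean promoter enrichment value, the genes with a TSS in the 15 widest domains, the 10 genes with the most distal peaks and the 10 with the highest mean promoter enrichment value. Members without a peak tied for lowest and were ordered by symbol, so those named are the last in the alphabet. Hox genes were described as groups. Six2, Fgf9, Uncx, Wnt4 and Cdh6 fall outside this rule and were chosen after their values were seen. Alternatives set beforehand were promoter windows of 500 and 2500 bp, a minimum −log10 q of 2, the 30000 peaks with the highest enrichment value, the pooled list, each replicate list alone, other overlap rules, distal windows of 25 and 100 kb, random lists matched on promoter CpG or on TSS density, motif windows of 100 bp, motif background 2 kb outside the peak, and domain gaps of 0 and 3 kb.

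The procedures were tested on simulated data. Among lists of 20 genes drawn from 21851, the promoter test called 75% of those set to 95% marked, 74% of those set to 35% marked and 0.5% of those left as drawn. The distal test called 93% of lists given 2 more peaks per gene and 1% of those left as drawn. With sites of the AP-1 motif put into 10% of 5000 shuffled sequences, a ratio of 2.15 was put in and 1.93 was recovered. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and plots used matplotlib 3.10.9.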

Results

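H3K4me2 peaks were available from 2 replicate pools of mouse kidney at embryonic day 16.5, a stage at which nephron progenitors, the branching ureteric bud, maturing nephrons, stroma and vessels are present together. The list of replicate 1 held 51473 peaks with a median width of 568 bp that covered 48.4 Mb, or 1.83% of the called bases of the chromosomes. The list of replicate 2 held 54225 peaks with a median width of 579 bp that covered 50.8 Mb, or 1.92%. The pooled list held 56458 peaks, and the replicated list, the main set below, held 40937 peaks with a median width of 917 bp. Read depth is unknown, since peak lists carry no counts.

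The replicates were compared to show how well peaks and their heights repeat between pools of embryos. Promoters of Ret, Synpo, Fgf9, Wnt4, Cdh6 and Pecam1 had peaks in both lists. Ret, the receptor for GDNF on the ureteric bud, had 46.6 in replicate 1 and 47.4 in replicate 2. Synpo, which encodes the podocyte protein synaptopodin, had 48.7 and 54.9, and Fgf9, a growth factor of nephron progenitors, had 36.1 and 38.3. Wnt4, which drives the forming nephron, had 39.7 and 26.7, and the cadherin gene Cdh6 had 19.7 and 35.3. Pecam1, an endothelial adhesion molecule, was weaker, with 2.35 and 5.23. Of the replicate 1 peaks, 41154 (79.95%, 95% interval 79.6 to 80.3%) were shared with replicate 2, and of the replicate 2 peaks 40780 (75.2%, 74.8 to 75.6%) were shared with replicate 1. Across the 40937 replicated peaks Spearman's rho of the enrichment value was 0.925, a value across peaks, which are not independent replicates. A peak absent from a replicate list entered as 0. Most peaks of this list were found in both replicates, a selection that can raise rho, and rho was lower over the pooled list, as given below. In the 25% of peaks with the lowest replicate 1 values rho was 0.256, against 0.694 in the 25% with the highest, among peaks present in both lists, so the order of weak peaks repeated poorly (quartering chosen after seeing the data). Every replicated peak had the coordinates of a pooled peak. Of the replicated peaks, 38446 overlapped a peak of both replicates by at least 1 bp and 2491 did not, 1542 having no peak in replicate 1 and 982 none in replicate 2.

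Peaks found in 1 replicate alone were narrow and lay mostly away from promoters. Replicate 1 had 10319 such peaks with a median width of 219 bp, against 805 bp for shared peaks, and 9.52% of them lay in promoters, against 44.7% of shared peaks. Replicate 2 had 13445, with a median width of 237 bp against 865 bp and 8.84% in promoters against 45.2%. The median enrichment value of peaks found alone was 3.36 in replicate 1 and 3.45 in replicate 2, and that of shared peaks 10.5 and 12.3. No test was made of these values, which have n = 2 lists.

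The distribution over the genome was examined to show where the mark lies. Promoters held 17261 of 40924 replicated peaks on the chromosomes (42.2%, 95% interval 41.7 to 42.7%), while promoters make up 2.94% of called bases, a ratio of 14.3. In the replicate lists the share was 36.9% ± 1.00 (SD, n = 2). Exons held 4.92% of replicated peaks, at 1.73 times their share of the genome, introns 30.9% at 0.771 times and intergenic sequence 22.0% at 0.406 times. Promoter peaks were also the widest, with a median of 1592 bp against 788.5 bp in exons, 615 bp in introns and 610 bp between genes. Their median enrichment value in the replicated list was 28.6, against 8.52 in exons, 5.20 in introns and 6.05 between genes. Of all replicated peaks 23663 (57.8%) were distal, at a median of 12.1 kb from the nearest TSS, and 90.2% of replicated peaks lay within 50 kb of a TSS. The promoter share depended on the list and on the promoter window, and was 33.0% in the pooled list and 28.5% with a 500 bp window.

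A promoter peak was found at 14793 of 21851 protein-coding genes (67.7%, 95% interval 67.1 to 68.3%), and at 68.1% ± 0.0906 (SD, n = 2) in the replicate lists. The 10 highest mean promoter enrichment values belonged to Trnp1, Dlk2, Nanos1, Mapre2, Rara, Srsf12, Gnal, Rasgef1c, Mfsd3 and Cyp46a1. Trnp1 on chromosome 4 had 64.1 ± 0.787 (SD, n = 2) and Cyp46a1 on chromosome 12 had 57.8 ± 4.16. Rara, the retinoic acid receptor alpha gene on chromosome 11, had 59.95 ± 0.704, and Dlk2 on chromosome 17 had 61.3 ± 11.3, so their order lies within the spread between replicates. Marked promoters had a median CpG ratio of 0.713 and unmarked promoters 0.163. With genes in 10 equal groups by promoter CpG, 3.93% were marked in the lowest group, 55.3% in group 4 and 99.5% in the highest.

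The gene lists were compared to show which cell types of the kidney, and which tissues outside it, had marked promoters. All 20 nephron progenitor genes were marked, among them Six2 (chromosome 17, TSS at 85688274; mean promoter enrichment value 24.3 ± 4.66, SD, n = 2), the transcription factor that maintains this population. In that list Dpf3 had the highest mean promoter enrichment value, 45.9 ± 4.03, followed by Spock2 at 40.1 ± 5.27, and Capn6 (7.97 ± 0.328) and Meox1 (9.25 ± 1.40) had the lowest. All 18 genes of the renal vesicle and early nephron were marked, from Dll1 (41.1 ± 6.44) and Ccnd1 (40.2 ± 3.03) to Emx2 (14.7 ± 1.53) and Pax8 (11.8 ± 2.60). All 20 podocyte genes were marked as well, with Synpo (51.8 ± 4.34) and Mafb (45.7 ± 6.97) highest and the slit diaphragm genes Nphs2 (12.1 ± 0.0297) and Nphs1 (6.38 ± 0.103) lowest. In the ureteric bud and collecting duct list 21 of 22 genes were marked.

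Within that list Ret (47.0 ± 0.531) and Wnt11 (40.4 ± 1.95) had the highest mean promoter enrichment values, the water channel gene Aqp2 had 3.63 ± 0.0952, and the uroplakin gene Upk1b had no peak. Of the renal stroma genes 19 of 20 were marked, with Ntn1 (41.9 ± 2.02) and Fat4 (37.7 ± 3.68) highest. Postn had 3.63 ± 0.0952, and the renin gene Ren1 had no peak. The equal values of Aqp2 and Postn lay near the medians of peaks found in 1 replicate alone (3.36 and 3.45), so both peaks were weak. Of the endothelium genes 19 of 20 were marked, with the VEGF receptor gene Kdr (39.7 ± 1.85) and Fli1 (32.4 ± 1.64) highest, Pecam1 at 3.79 ± 2.03 and no peak at the von Willebrand factor gene Vwf. By Fisher's exact test each of these lists had more marked genes than other protein-coding genes, with adjusted p = 0.00170 for nephron progenitor and podocyte genes, 0.00429 for the early nephron, 0.00889 for the ureteric bud and 0.0107 for stroma and endothelium. All 24 housekeeping genes were marked (adjusted p = 5.109e-04, Fisher's exact test), among them Rps18 (48.3 ± 4.61) and Ubc (46.3 ± 2.36) at the upper end and the X-linked Pgk1 (19.3 ± 2.20) and Hprt (16.6 ± 1.09) at the lower.

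Genes of mature tubules were called neither higher nor lower than other genes. In the proximal tubule list 16 of 22 genes were marked (adjusted p = 0.820, Fisher's exact test). Gatm (31.3 ± 2.69) and Ass1 (31.3 ± 0.900) had the highest mean promoter enrichment values there, while the sodium-coupled transporter genes Slc5a2 and Slc5a12 had no peak. In the list of loop of Henle and distal tubule genes 13 of 22 were marked (adjusted p = 0.428, Fisher's exact test), with Cldn10 (42.4 ± 1.76) and Ppp1r1b (41.7 ± 0.123) highest and no peak at the uromodulin gene Umod or the calcium channel gene Trpv5. Against random lists matched on promoter CpG, proximal tubule genes were marked at 72.7% against a mean of 49.8% (adjusted p = 0.0731, permutation test), and their covered length within 5 kb, a measure chosen after seeing the data, was greater (1885 against 1174 bp, adjusted p = 0.0357, permutation test).

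Blood cell genes were marked less often than other genes, though neither call held with promoter CpG matched. Of the macrophage and leukocyte genes 3 of 20 were marked (adjusted p = 1.977e-05, Fisher's exact test), including Ikzf1 (46.5 ± 1.15) and Coro1a (32.9 ± 6.39), while Spi1, which encodes PU.1, and Tyrobp had no peak. Of the erythroid genes 7 of 19 were marked (adjusted p = 0.0107, Fisher's exact test), with Epor (35.9 ± 1.11) and Klf1 (33.6 ± 6.19) highest. Spta1 and Trim10 had no peak. Klf1 has a promoter CpG ratio of 0.0783 and 7 TSS within 50 kb, and Epor has 0.282 and 9, their own included. The peaks counted for them can belong to a neighbour. Against lists matched on promoter CpG both calls ended and that of erythroid genes turned, with 36.8% marked against 31.6% (adjusted p = 0.770, permutation test), and macrophage genes stood at 15% against 33.1% (adjusted p = 0.190, permutation test). Genes of neural crest, glia and neurons of the kidney nerve supply were marked at 15 of 20 (adjusted p = 0.695, Fisher's exact test), with Ret and Ascl1 (44.6 ± 1.52) highest and none at Th or S100b.

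Among tissues outside the kidney, fewer genes were marked in the lists of spermatogenic cells (3 of 20), hepatocytes (4 of 20), keratinocytes (5 of 20), cardiac muscle (7 of 20), pancreas (7 of 20) and skeletal muscle (8 of 20). Their adjusted p by Fisher's exact test was 1.977e-05, 1.218e-04, 5.109e-04, 0.00716, 0.00716 and 0.0192. Unmarked members named by the rule were Tnp2 and Tssk2 of spermatogenic cells, Tat and Ttr of hepatocytes, Tgm3 and Sprr1b of keratinocytes, Tbx5 and Tnnt2 of cardiac muscle, Prss2 and Sst of pancreas, and Tnni2 and Tnnt3 of skeletal muscle. The highest mean promoter enrichment values were at Spag16 (25.1 ± 0.636) and Zpbp (24.9 ± 6.97) of spermatogenic cells, Foxa2 (19.9 ± 3.56) and Trf (8.76 ± 0.124) of hepatocytes, Lor (40.6 ± 7.14) and Perp (35.6 ± 3.22) of keratinocytes, Ryr2 (42.3 ± 3.39) and Myl4 (26.7 ± 8.40) of cardiac muscle, Nkx6-1 (24.6 ± 4.38) and Bhlha15 (20.7 ± 1.498) of pancreas, and Actn3 (39.8 ± 3.88) and Mylpf (34.5 ± 10.8) of skeletal muscle. Lor and Mylpf have low promoter CpG ratios (0.0951 and 0.0815), and the peaks counted for them can belong to a neighbour. Brain neuron genes were marked at 17 of 20 (adjusted p = 0.190, Fisher's exact test), with Satb2 (43.9 ± 0.429) and Bcl11b (40.9 ± 1.66) highest. Neurod6 and Slc17a6 had no peak.

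**Figure D1:**
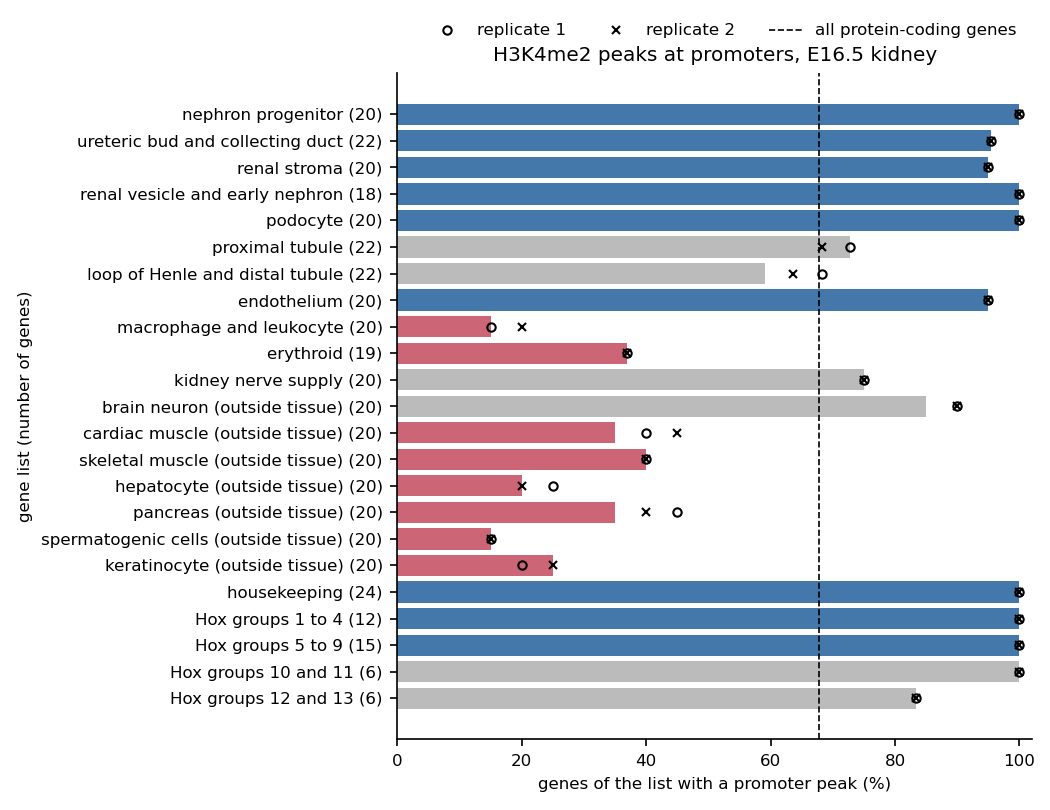
Share of genes with a promoter peak in each gene list (x axis, percent), with bars for the replicated list (blue, higher and red, lower than other genes at an adjusted p under 0.05 by Fisher's exact test, grey otherwise), circles and crosses for the replicate lists and a dashed line at 67.7% for all protein-coding genes. The kidney compartment lists other than mature tubules stand at 95% to 100%, and the macrophage and spermatogenic lists at 15%.

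Altogether 9 lists were higher, among them Hox groups 1 to 4 and 5 to 9, whose genes are not independent, and 8 lower. Against random lists matched on promoter CpG in 10 groups of genes, 4 of these 17 calls remained: higher marking of renal stroma (adjusted p = 0.0144) and endothelium (adjusted p = 0.00529), and lower marking of pancreas (adjusted p = 0.0193) and spermatogenic genes (adjusted p = 4.6e-04), all by a permutation test. With a 2500 bp window the cardiac muscle (adjusted p = 0.259) and skeletal muscle (adjusted p = 0.127) lists were no longer lower by Fisher's exact test. In the pooled list this held for cardiac muscle and pancreas (adjusted p = 0.114 for both, Fisher's exact test), and with the 30000 strongest peaks the ureteric bud (adjusted p = 0.0917) and stroma (adjusted p = 0.118) lists were no longer higher by the same exact test.

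Many Hox genes, which pattern the body axis and of which paralog groups 10 and 11 act in kidney formation, lay in the widest domains of the mark. All 12 genes of paralog groups 1 to 4, all 15 of groups 5 to 9 and all 6 of groups 10 and 11 were marked, and 5 of the 6 genes of groups 12 and 13, the exception being Hoxc12. Hoxd1 (43.0 ± 2.58, SD, n = 2) and Hoxa4 (42.2 ± 0.559) had the highest mean promoter enrichment values of groups 1 to 4, Hoxd9 (35.5 ± 0.841) and Hoxb9 (32.7 ± 5.37) of groups 5 to 9, Hoxd10 (35.5 ± 0.841) and Hoxc11 (30.0 ± 1.957) of groups 10 and 11, and Hoxd13 (25.3 ± 9.20) and Hoxa13 (18.1 ± 1.53) of groups 12 and 13. The lowest were Hoxb1 (13.3 ± 0.186) and Hoxd4 (18.1 ± 3.84), Hoxc6 (13.5 ± 1.70) and Hoxc8 (19.9 ± 1.62), Hoxc10 (17.5 ± 7.81) and Hoxd11 (20.8 ± 1.31), and Hoxb13 (7.04 ± 0.210). These orders do not all hold in the replicated list, where the promoter enrichment value was 40.2 at Hoxb5, Hoxb6, Hoxb7 and Hoxb8, 36.2 at Hoxb9 and 32.5 at Hoxd9, and 36.6 at Hoxc10, 35.9 at Hoxc11 and 32.5 at Hoxd10. Each gene took the value of the whole peak at its promoter, so genes under a wide peak share its value. In the replicated list Hoxb5 to Hoxb8 lay in 1 peak (96276200 to 96330880). Hoxc10 shared 1 peak with Hoxc9 there, while both replicate lists had separate peaks at these genes. Hoxd9 and Hoxd10 lay in the same peak, and so had equal values, in the replicated list and in both replicate lists. Adjusted p by Fisher's exact test was 0.0176 for groups 1 to 4, 0.00881 for groups 5 to 9, 0.226 for groups 10 and 11 and 0.702 for groups 12 and 13. Neighbouring Hox genes can be marked by 1 shared peak and are not independent, so these p-values are too small. Lists of 6 genes leave little room for a difference from 67.7%.

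The widest domain, 59.3 kb on chromosome 11 from 96276200 to 96335511, held TSS of Hoxb3, Hoxb4, Hoxb5, Hoxb6, Hoxb7 and Hoxb8. Domains of 50.3 kb on chromosome 6 (52199930 to 52250221) and 44.3 kb on chromosome 2 (74672652 to 74717000) held TSS of Hoxa3, Hoxa5, Hoxa6, Hoxa7, Hoxa9, Hoxa10 and Hoxa11, and of Hoxd3, Hoxd8, Hoxd9, Hoxd10, Hoxd11 and Hoxd12, and 31.8 kb on chromosome 15 (102953635 to 102985463) those of Hoxc9, Hoxc10 and Hoxc11. Hoxa1, Hoxa4, Hoxa13, Hoxb1, Hoxb9, Hoxb13, Hoxc4, Hoxc12, Hoxc13, Hoxd1 and Hoxd13 had no TSS in any of the 15 widest domains. In the replicate lists the domains over these HoxA, HoxD and HoxC genes were 50.3 ± 0.155, 44.3 ± 0.0120 and 31.6 ± 0.284 kb wide (SD, n = 2), and the HoxB domain 65.1 ± 7.81 kb. Outside the Hox clusters the widest were at Nr2f2 (28.5 kb, chromosome 7, 70344121 to 70372588), the stroma gene Meis2 (24.5 kb, chromosome 2, 116052115 to 116076631), the ureteric bud gene Gata3 (24.5 kb, chromosome 2, 9866029 to 9890479), Pax2, which is needed for kidney formation (19.6 kb, chromosome 19, 44745737 to 44765353), and Bahcc1 (19.1 kb, chromosome 11). The neighbours Foxc2 and Foxl1 shared 18.7 kb on chromosome 8, and Emx2 had 17.8 kb on chromosome 19. The other 4 of the 15 widest were further Hox segments, at Hoxc5, Hoxc6 and Hoxc8 (26.3 kb), Hoxd3 and Hoxd4 (21.6 kb), Hoxb2 and Hoxb3 (18.9 kb) and Hoxa2 (18.8 kb). These domains also held TSS of Gm28308 (HoxA), Gm28230 (HoxD), 5730596B20Rik (at Hoxa2), and 4930412O13Rik and 9230102O04Rik (at Gata3). In the replicate lists the domain at Hoxc5, Hoxc6 and Hoxc8 was narrower (14.3 ± 4.44 kb), and that at Foxc2 and Foxl1 was 9.67 kb in replicate 1 and 18.4 kb in replicate 2. The domain at Hoxb2 and Hoxb3 was 17.3 kb in replicate 2 and part of the widest HoxB domain, 70.6 kb, in replicate 1. Of 32794 domains 77 reached 10 kb. With no gap joined, 7 of the 15 stayed among the widest.

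**Figure D2:**
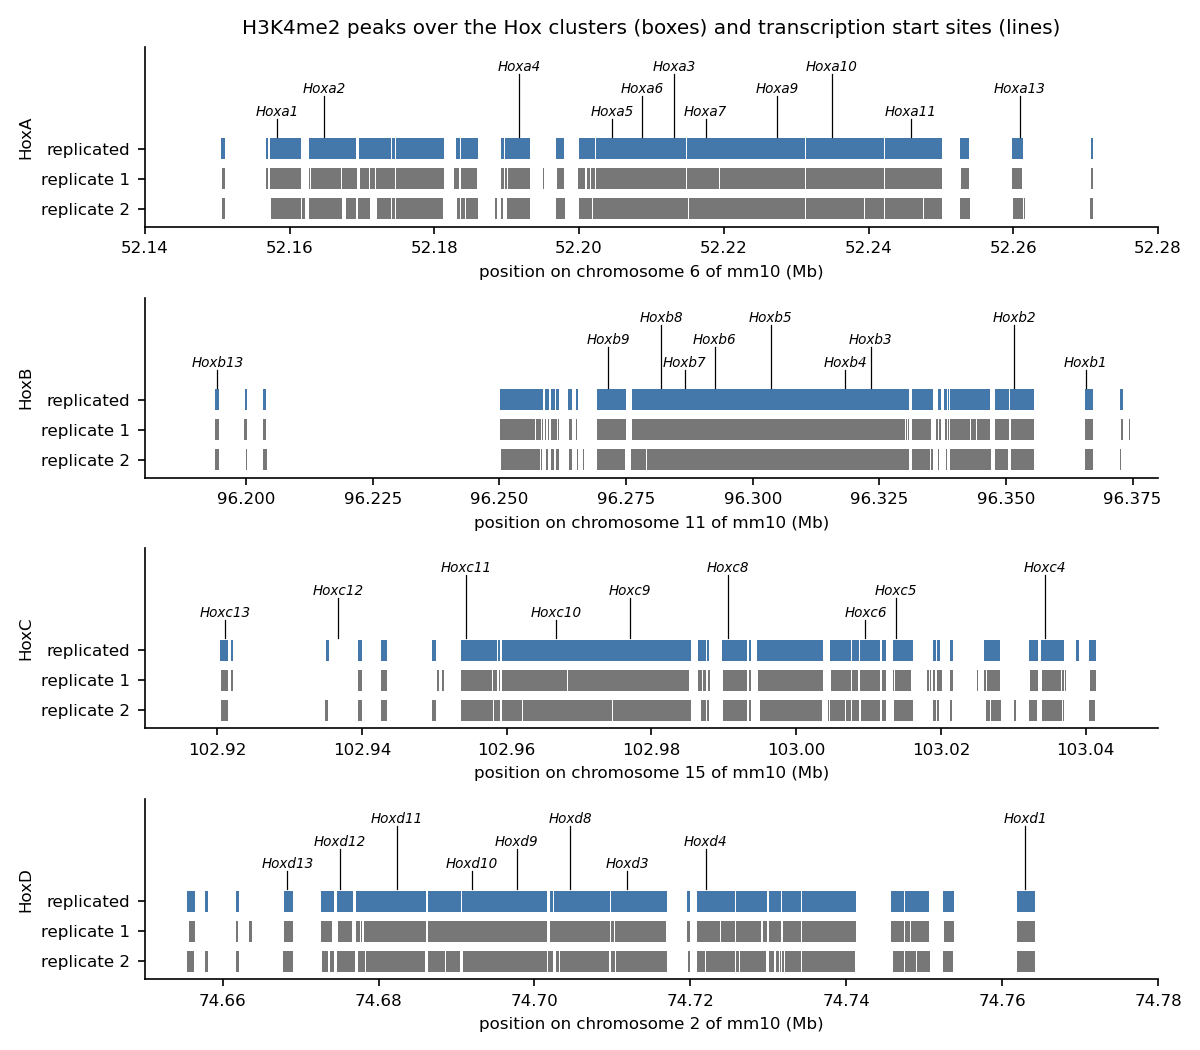
Peaks over the HoxA, HoxB, HoxC and HoxD clusters (x axis, position in Mb on mm10), with boxes for peaks of the replicated list and of each replicate and lines at the principal TSS of each Hox gene. Near-continuous peaks run over the middle of each cluster, and Hoxc12 lies in a gap of the replicated list.

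Distal peaks within 50 kb were counted to show whether loci of cell type genes hold more of the mark away from promoters. Nephron progenitor genes had a mean of 5.4 distal peaks, against 1.63 for random lists, with 15 at Uncx, 11 at Hoxd11, 10 at Hoxa11 and 7 at Six2. Hoxa11 and Hoxd11, and Hoxb7 (7 distal peaks) on the ureteric bud list, are also members of Hox lists. No distal comparison left such shared members out. Ureteric bud genes had a mean of 4.00, endothelium genes 3.80, stroma genes 3.75, early nephron genes 3.67 and podocyte genes 2.90. Housekeeping genes also lay above random lists, with 3.58. Adjusted p by the permutation test was 9.2e-05 (adjusted from the smallest p possible) for nephron progenitors, 4.6e-04 for the ureteric bud, 9.775e-04 for stroma and endothelium, 0.00304 for the early nephron, 0.0402 for podocytes and 0.00107 for housekeeping genes. In the replicate lists, which hold more peaks, the nephron progenitor mean was 7.58 ± 0.0354 and the ureteric bud mean 6.11 ± 0.804 (SD, n = 2).

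The Hox lists had means of 9.33 (groups 1 to 4), 11.8 (groups 5 to 9), 11.7 (groups 10 and 11) and 8 (groups 12 and 13), each with an adjusted p of 9.2e-05 by the permutation test. Neighbouring Hox genes share windows and are not independent, so these p-values are too small. With distal peaks over 5 kb from every TSS the ratios to the random mean fell from 5.74 to 2.76, 7.25 to 1.80, 7.15 to 2.04 and 4.91 to 2.04, and the cause was not tested. The 10 genes with the most distal peaks were Hoxc8, with 18, and genes of the histone cluster on chromosome 13, namely Hist1h2bh and Hist1h3f with 21 each, Hist1h3g and Hist1h4f with 20, Hist1h1d, Hist1h2af, Hist1h4h and Btn2a2 with 19 and Btn1a1 with 18. These histone and butyrophilin genes also share windows.

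No other list passed the threshold by the permutation test. Proximal tubule genes had a mean of 2.59 (adjusted p = 0.0954, permutation test) and skeletal muscle genes 2.50, followed by brain neurons with 2.35, loop of Henle and distal tubule with 2.32, kidney nerve supply with 2.20, pancreas with 2.10 and cardiac muscle with 2.00. Erythroid genes had 1.74, hepatocyte genes 1.45, spermatogenic genes 1.40, macrophage genes 1.25 and keratinocyte genes 0.750 (adjusted p = 0.0707, permutation test). Podocyte genes were no longer above random lists drawn from genes with a promoter peak (adjusted p = 0.212, permutation test), nor within 100 kb (adjusted p = 0.0620) or with the 30000 strongest peaks (adjusted p = 0.276). Within 25 kb the proximal tubule (adjusted p = 0.00322), loop of Henle (adjusted p = 0.0124), brain neuron (adjusted p = 0.0112) and skeletal muscle (adjusted p = 0.00941) lists also rose above random lists by the permutation test, so the excess was not confined to kidney lists. In either replicate list alone proximal tubule genes were higher (adjusted p = 0.00744 and 0.00912) and keratinocyte genes lower (adjusted p = 0.0167 and 0.0385) by the permutation test. In the replicated list the same held for both, proximal tubule (adjusted p = 0.0490) and keratinocyte genes (adjusted p = 0.0249), against random lists matched on the number of TSS within 50 kb by the permutation test. With distal peaks over 5 kb from every TSS, an alternative chosen after seeing the data, 5 of the 11 lists remained above random lists: nephron progenitor, ureteric bud, stroma, early nephron and Hox groups 1 to 4.

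**Figure D3:**
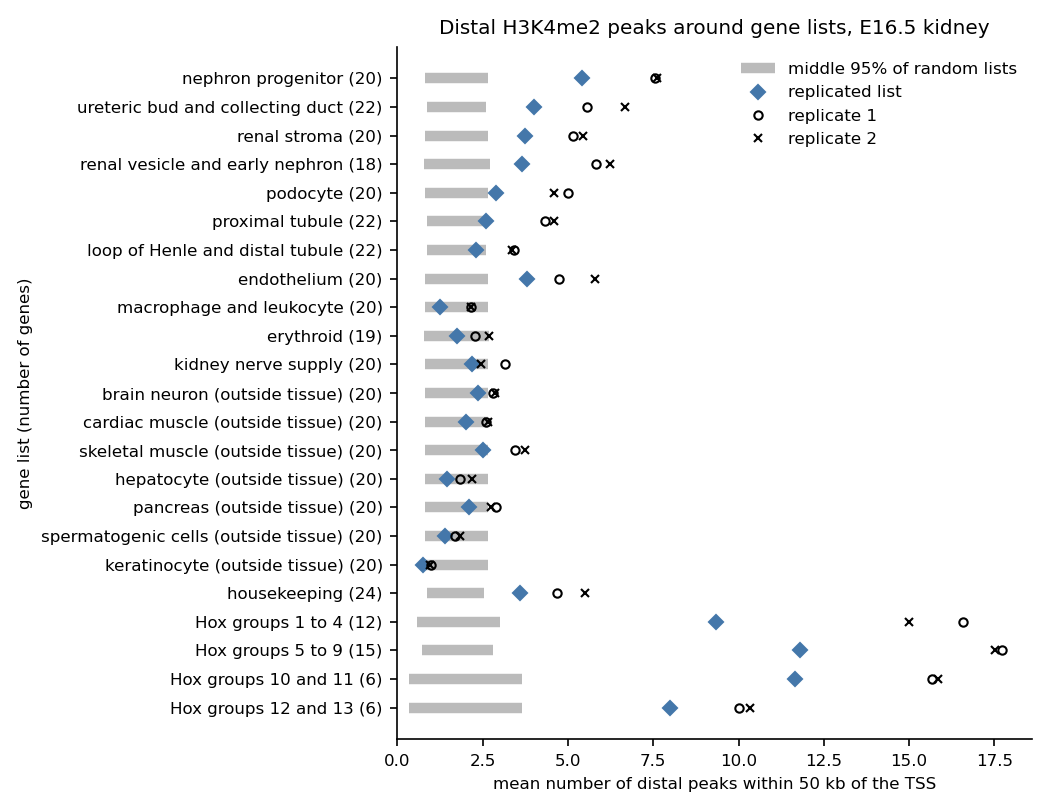
Mean number of distal peaks within 50 kb of the TSS for each gene list (x axis), with diamonds for the replicated list, circles and crosses for the replicate lists and grey bars for the middle 95% of 100000 random lists scored on the replicated list. Nephron progenitor genes stand at 5.4 and the Hox lists between 8 and 11.8.

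Motifs near summits of distal peaks were compared with shuffled sequence to show which transcription factor families have sites there. Peaks counted as distal by their midpoint, so the summit of a wide peak can lie within 1 kb of a TSS. Such windows were not left out. The consensus of CTCF, which organises chromatin loops, was found in 3.21% of 23656 distal windows against 0.258% of shuffled windows, a ratio of 12.5 (95% interval 9.60 to 16.2; 8.96 ± 0.498 in the replicate lists, SD, n = 2). The CTCF ratio was 7.34 against windows 2 kb outside the peaks. The consensus of HNF1, whose member HNF1B acts in the ureteric bud and nephron, had a ratio of 4.20 (2.39 to 7.37; 6.09 ± 1.29), from 63 windows, and 8.375 in the pooled list and 14.5 with the 30000 strongest peaks. With the strongest peaks the share of windows with the HNF1 match was lower (0.210% against 0.266%). The ratio rose there because fewer shuffled windows matched (0.0145% against 0.0634%). That of WT1, a regulator of nephron progenitors and podocytes, had 2.50 (2.29 to 2.73; 2.66 ± 0.0150). The posterior HOX consensus had 1.497 (1.29 to 1.73; 1.47 ± 0.0248) and that of SIX1/SIX2 1.23 (1.14 to 1.33; 1.201 ± 0.0183). The SIX1/SIX2 ratio was 1.19 in the list of replicate 2 alone, under the minimum for a call. Adjusted p by Fisher's exact test was 2.242e-155, 9.351e-08, 5.402e-104, 1.295e-07 and 4.273e-07 for these motifs.

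In all 13 of 23 motifs were called. The others were NRF1 (12.0, from 36 windows; 6.86 ± 2.79 in the replicate lists, SD, n = 2), PU.1 (2.10), MEF2 (2.07), the myogenic E-box (1.95), FOX (1.93), TEAD (1.74), ESRR (1.67) and ETS (1.61), and their highest adjusted p was 4.773e-06 by Fisher's exact test, for ESRR. AP-1 (1.026), GATA (1.10), NFI (1.05), TCF/LEF (0.962) and the neuronal E-box (1.29) were not called, nor were AP-2 (0.855), PAX2/PAX8 (0.801), HNF4 (0.785) and GRHL (0.723). REST had 12 windows and none after shuffling (adjusted p = 7.477e-04, Fisher's exact test), so it has no ratio and was not called for that reason alone. It passed in the pooled list (ratio 14), with a −log10 q of at least 2 (ratio 12) and in the list of replicate 2 alone (ratio 11). These REST ratios rest on very few shuffled windows with a match (0.00264%, 0.00426% and 0.00289%). Matches of GRHL (adjusted p = 4.075e-08) and HNF4 (adjusted p = 0.0324, both Fisher's exact test) were fewer than after shuffling, but no such difference was called against windows 2 kb outside the peaks (ratios 1.029 and 0.982). A consensus match does not show which factor, if any, was bound. Against windows 2 kb outside the peaks 9 of the 13 calls remained, with ratios under the minimum for SIX1/SIX2 (1.10), FOX (1.18) and MEF2 (1.11) and ratios above it for NFI (2.18), AP-2 (1.24) and REST (from 12 windows), while ESRR turned to 0.625 (adjusted p = 7.419e-10, Fisher's exact test). Within 100 bp of the summit the CTCF ratio was 0.833 (adjusted p = 0.563, Fisher's exact test) and the calls of ETS and NRF1 ended. The NRF1 ratio fell to 1.71 against windows 2 kb outside the peaks, and the neuronal E-box passed in the pooled list (1.69) and in the list of replicate 2 alone (ratio 2). In the 3459 windows without repeat bases, chosen after seeing the data, 6 calls remained, and those of HNF1 (6, adjusted p = 0.286) and posterior HOX (1.47, adjusted p = 0.221) were among the calls that ended by Fisher's exact test, while the WT1 ratio fell to 1.54.

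**Figure D4:**
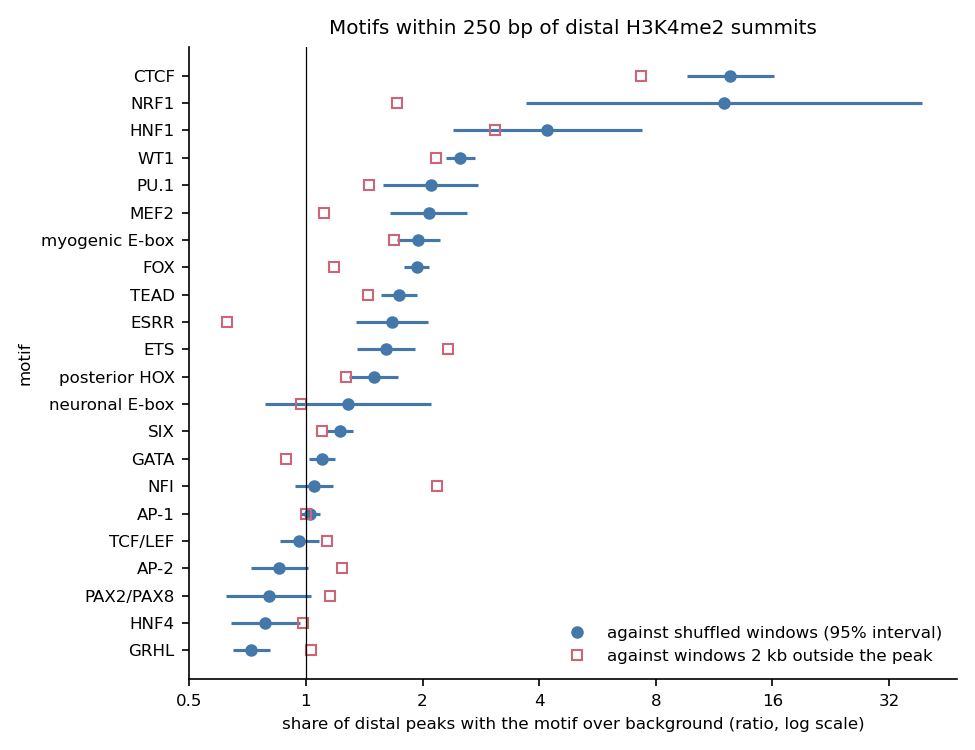
Ratio of the share of distal windows with each motif to the background share (x axis, log scale), for 23656 windows of 250 bp on either side of the summit, with filled circles and 95% intervals against shuffled sequence and open squares against windows 2 kb outside the peak. CTCF stands highest on both backgrounds, and ESRR falls on opposite sides of 1.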

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

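The tests of peaks found in 1 replicate alone, of the pancreas and spermatogenic lists taken separately and of the podocyte and endothelium lists taken separately were chosen only after the results were seen, as were the covered length against lists matched on CpG and the count of distal peaks over 5 kb from every TSS.

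Signal outside the chromosomes drew attention because the comparisons by class, gene and motif leave it out: 13 replicated peaks lay on unplaced or unlocalised scaffolds. Of these, 5 lay on a scaffold assigned to chromosome X and 3 on a single scaffold assigned to chromosome 4, and the replicate lists held 14 and 13 such peaks.

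Promoter marking differed between gene lists, being higher in the lists of kidney compartments other than mature tubules and lower in most lists of other tissues, and promoter CpG content is a candidate explanation. Against random lists matched on promoter CpG 2 of the 8 lower lists stayed lower, so CpG content may account for the calls of macrophage, erythroid, cardiac, skeletal muscle, hepatocyte and keratinocyte genes, though macrophage genes remained at 15% marked against 33.1% in matched lists and hepatocyte genes at 20% against 39.6%. The pancreas list stayed lower (35% marked against 59.1%), as did the spermatogenic list (15% against 60.4%). Their larger adjusted p was 0.0193 by a permutation test. Both were picked for staying lower in this same comparison, so it cannot exclude CpG content for them. Matching in 10 groups may also leave CpG differences within a group. In the replicate lists pancreas genes were marked at 45% and 40%. Of the higher kidney lists, nephron progenitor, ureteric bud, early nephron and podocyte genes were no longer higher (adjusted p = 0.712, 0.279, 0.770 and 0.770, permutation test). The share marked is near 100% for CpG-rich genes and cannot show an excess there, so the covered length within 5 kb of the TSS was also compared. All 6 of the kidney compartment and endothelium lists (nephron progenitor, ureteric bud, stroma, early nephron, podocyte, endothelium) stayed above matched lists in covered length. For nephron progenitors it was 6293 bp, against a matched mean of 2558 bp. Housekeeping (adjusted p = 9.967e-04) and proximal tubule genes (adjusted p = 0.0357, permutation test) did so too. This argues against CpG content within 500 bp of the TSS as the whole cause of the wide coverage. CpG content farther out within the 5 kb was not matched and stays open. The covered length does not bear on the share marked, which is another measure. Whether CpG-rich promoters carry the mark or are only detected more readily was not tested, and no biological explanation was tested, since the design has 1 group.

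Distal peaks were more frequent around 6 lists of kidney compartments and endothelium, though also around housekeeping genes and, under some settings, proximal tubule genes (adjusted p = 0.0490 by a permutation test with TSS density matched), and fragments of wide promoter domains could produce this. With distal peaks over 5 kb from every TSS, 4 of the 6 lists stayed above random lists. For nephron progenitors the ratio to the random mean was 3.32 before and 3.37 after. This argues against fragments within 5 kb of a TSS as the whole cause there. Domains at list members such as Pax2 (19.6 kb) and Gata3 (24.5 kb) were wide, and fragments of them can lie beyond that cutoff. The count therefore cannot exclude fragments farther out. For podocyte genes the ratio was 1.78 before and 2.02 after (adjusted p = 0.0711) and for endothelium genes 2.33 and 1.84 (adjusted p = 0.122, both by a permutation test). Their calls ended with fewer peaks left to count, and fragments at any distance stay open for them. Marked surroundings of marked promoters were tested with random lists of genes with a promoter peak, and 5 of the 6 lists stayed higher, all but podocyte genes (mean 2.90, random mean 2.03). No biological explanation was tested.

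Peaks found in 1 replicate alone numbered 23764 over both lists, and calls near the threshold are a candidate explanation. Of these peaks 99.6% lay below the median −log10 q of their list, and among the 25% of peaks with the highest −log10 q in either list none stood alone. This is consistent with weak peaks being called in 1 library and missed in the other, but 64.7% (replicate 1) and 71.3% (replicate 2) of them had a −log10 q of at least 2, so nearness to the threshold itself stays open. Depth differences between the libraries stay open, since the lists carry no counts, and no biological explanation was tested.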

How the results depend on the processing

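Alternatives with distal peaks over 5 kb from every TSS, windows without repeat bases and shared list members left out were chosen after seeing the data. Under 1 bp of overlap, 50% of both peaks, a −log10 q of at least 2 and the 30000 strongest peaks, 83.6%, 66.7%, 83.6% and 91.5% of replicate 1 peaks were found in replicate 2, and 78.5%, 63.3%, 77.8% and 92.6% of replicate 2 peaks in replicate 1. Rho was 0.869 over pooled peaks with 0 where absent and 0.939 over the 30000 strongest. The promoter share of peaks was 28.5% and 52.6% with windows of 500 and 2500 bp, 50.4% of covered base pairs, 54.0% of the 30000 strongest, 33.0% in the pooled list and 36.2% to 37.6% leaving out a replicate. The share of genes with a promoter peak was 67.0% and 68.9% with those windows, 66.4% with the 30000 strongest, 68.7% in the pooled list and 68.2% to 68.1% leaving out a replicate. The 17 promoter calls came to 4 with lists matched on promoter CpG, where erythroid genes turned from below to above their random lists (36.8% marked), and to between 15 and 17 otherwise. The 11 distal calls came to 5 with peaks over 5 kb from every TSS and to between 10 and 15 otherwise. The 13 motif calls came to 6 in windows without repeat bases, of which 3459 were left, and to between 10 and 15 otherwise. CTCF turned to 0.833 within 100 bp of the summit and ESRR to 0.625 against windows 2 kb outside the peak. Peaks found alone lay in promoters at 8.51% with 1 bp of overlap and 14.3% for the 30000 strongest, against 9.18%. Of the 15 widest domains 7 stayed with 0 bp joined, 12 with 3 kb, 13 in the pooled list and 11 to 13 leaving out a replicate. For single lists, 188 of the promoter values kept their call or lack of one, 18 lost a call and 1 turned. Of the distal values 209 kept it, 9 lost a call and 12 gained one. Of the motif values, without REST, which had no ratio to compare, 157 kept it, 13 lost a call, 4 gained one and 2 turned. Except where fewer windows or peaks were left or the matching on CpG shows it, the cause was not tested. Unknown depth limits all statements that a promoter had no peak.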

Other observations

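Gene families were described after the results were seen, by symbol, and none of the values in these paragraphs was planned. All 19 Sox factor genes had a promoter peak, as did 18 of 19 Wnt ligand genes (all but Wnt8b), 20 of 22 Fgf ligand genes (all but Fgf21 and Fgf23), 38 of 44 Fox factor genes and 345 of 394 Zfp zinc finger genes. All 46 Nduf genes of respiratory complex I and 76 of 79 ribosomal protein genes were marked, the exceptions being the paralogs Rpl10l, Rpl39l and Rpl3l. At the other end, 4 of 1134 olfactory receptor genes, 1 of 329 vomeronasal receptor genes and 1 of 42 beta-defensin genes were marked. Cytochrome P450 genes were marked at 25 of 98, keratin genes at 9 of 49, clustered protocadherin genes at 17 of 57 and claudin genes at 15 of 33. Solute carrier genes were marked at 291 of 371, with Slc12a1 and Slc12a3 of the loop of Henle and distal tubule list among those unmarked. By Fisher's exact test with adjustment over 17 families, 8 were higher, 7 lower and 2 not called, namely T-box (10 of 13) and Bmp (9 of 11) genes. Promoter CpG was not matched for these families, so its part in their calls was not tested.

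The X chromosome had 6.37 replicated peaks per Mb of called bases, below the range of the autosomes (11.8 to 25.7), and 52.3% of its protein-coding genes were marked, against 56.2% to 81.6% on the autosomes. In the replicate lists the X chromosome had 7.82 and 7.74 peaks per Mb. Chromosome Y had 6 replicated peaks. The number of X copies in the pools was not taken into account, so less marking and lower detection on X cannot be told apart. Chromosome 11 had the highest density.

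CTCF sites lay beside the summits of distal peaks and seldom under them. Of 998 CTCF matches within 500 bp of a distal summit, 36 (3.61%) lay within 100 bp and 741 (74.2%) between 100 and 250 bp, with a median distance of 183.5 bp. By comparison 25.5% of WT1 matches, 23.1% of TEAD matches and 18.7% of AP-1 matches lay within 100 bp. HNF1 matches were also sparse there, with 13 of 123. REST had 14 matches, of which 1 lay within 100 bp.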
